A study of Mus musculus with 5 samples.

How the data were processed

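Chromatin of double positive (DP) thymocytes, the immature CD4 and CD8 expressing T cells of the thymus, was profiled in C57BL/6 mice 4 to 6 weeks old. The series describes 5 samples, 1 per assay: DNase I hypersensitivity and chromatin immunoprecipitation for HEB, TCF1, H3K9me3 and H3K27ac. Region lists of 3 of them, DNaseI, HEB and TCF1, were analysed, and the 2 histone samples were not analysed here. No assay had a replicate, so no value carries a biological error.

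The 3 assays analysed were sequenced on a SOLiD instrument, per the labels' protocols. DNase I fragments came from short digests of intact nuclei and were size-selected on a gel, and the HEB and TCF1 chromatin was crosslinked and sonicated, per the labels' protocols. HOMER 6.1 and the mouse build mm9 are named in the submitters' processing notes, which do not say which step HOMER served. The aligner, the calling thresholds, the control libraries and the library totals are not given in the sources used here. Sequencing depth is therefore unknown, and no depth-based limit was put on regions missing from a list.

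Each list deposited by the authors gives a chromosome, a start, an end and a whole-number score per region. The score deposited by the authors has no stated unit. Scores were compared, ranked, stratified or filtered only within their own list, and no score of 1 list was set against a score of another. The closing section weighs hypotheses that depend on the scale of the score. HEB regions were all 201 bp and TCF1 regions all 183 bp, whereas DNaseI regions ran from 180 to 7846 bp, with 26.4% at exactly 201 bp. In the DNaseI list the score followed the width (Spearman's rho 0.94 across regions, which are not independent replicates). No list held duplicated or overlapping regions.

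Positions are mm9 coordinates counted from 1. The gene table used for names is of assembly GRCm38.p6, another build, so regions were not assigned to genes, promoters, introns or sequence motifs. The comparisons planned on annotation, gene lists and motifs were therefore not run. Chromosome lengths were taken as the span from the first to the last region of any list, 2.57 Gb in all.

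Overlap of 2 lists was counted as at least 1 bp. Observed overlap was compared with 1000 random permutations of the positions of the factor regions along their own chromosomes with widths kept, called placements (two-sided; the smallest p such placements can give is 0.002). Assembly gaps and unmappable sequence were not masked, which makes the placed overlap lower and the fold over it higher. Co-occupancy of HEB and TCF1 was tested among DNaseI regions, with the TCF1 mark permuted 10000 times within strata of chromosome, width decile and score decile (two-sided; smallest p 0.0002). It was summarised as a Mantel-Haenszel odds ratio over width deciles. The share in DNaseI regions was compared by two-sided Fisher's exact tests. Scores were compared by the difference of medians with 100000 permutations (two-sided; smallest p 1e-05) and 95% bootstrap intervals from 2000 resamples. Benjamini-Hochberg adjustment covered the 9 score comparisons together and the pair of share tests together. Clustering was the share of regions with another region of the same list within 10 kb, against 1000 placements. Shares carry 95% Wilson intervals and densities exact Poisson intervals, which cover counting error only. Regions of a list are not replicates of cells, so each p-value describes these lists and not the spread between animals.

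The regions named were fixed by rule before the data were examined: the 10 windows of 100 kb, on a fixed grid, with the most HEB plus TCF1 regions (ties by DNaseI regions, then by position), and the 5 highest-scoring regions of each list. Other overlap rules, stricter scores, autosomes alone, local shifts of 20 to 200 kb and other neighbour distances were tried as alternatives. On simulated lists with no effect, 3% of 100 overlap tests of the HEB and DNaseI comparison (4930 regions) and 2% of 100 co-occupancy tests (48320 regions) fell under 0.05. A simulated HEB share of 30% on DNaseI regions came back as 30.9% (1.40% placed), and a simulated co-occupancy odds ratio of 4 as 4.08. With no effect, 0% of 100 score tests (4930 HEB regions) and 5% of 100 clustering tests (3546 TCF1 regions) fell under 0.05. A score shift of 3 was found in 100% of simulations. The lists with no effect for overlap and clustering came from the same random placement as the tests. Co-occupancy marks with no effect depended on width decile only. These rates therefore check the computation and do not cover clustered regions or marks that follow the score. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6.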

Results

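Open chromatin and the binding of HEB and TCF1 were mapped in DP thymocytes. HEB is an E protein, encoded by Tcf12, that binds E-box sequences, and TCF1 is the HMG-box factor encoded by Tcf7. Both are known regulators of early T cell development. The series title names CapStarr-seq, a method that measures enhancer activity, and the region lists were compared here to ask where both factors lay relative to open chromatin and to each other. The DNaseI list held 48320 regions that covered 0.845% of the chromosome span, with a median width of 315 bp. The HEB list held 4930 regions and the TCF1 list 3546 regions, each list from 1 sample. Scores had a median of 16 (quartiles 10 and 33) for DNaseI, 11 (10 and 15) for HEB and 11 (9 and 14) for TCF1.

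The first comparison asked where both factors lay relative to open chromatin. Most TCF1 regions lay in DNaseI regions, with 3010 of 3546, or 84.9% (95% Wilson interval 83.7 to 86.0%). HEB regions did so less often, with 1701 of 4930, or 34.5% (33.2 to 35.8%). The difference of 50.4 percentage points had a 95% interval of 48.6 to 52.2 points. With scores above each list's median, where the shares were 79.7% and 52.4%, it was 27.3 points (24.3 to 30.3). Random placement put 1.33% of TCF1 regions and 1.32% of HEB regions in DNaseI regions, so observed overlap was 63.8-fold and 26.1-fold above placement (two-sided permutation of positions, p = 0.002 for each, the smallest possible). Against local shifts of 20 to 200 kb, which keep the regional density of open chromatin, these values were 22.2-fold and 12.4-fold (p = 0.002 each by permutation of positions). With a gap of up to 500 bp allowed they were 28.8-fold and 12-fold, and with scores above each list's median 92.6-fold and 60.4-fold. That score filter also removes DNaseI regions, and the placed shares under it were 0.861% for TCF1 and 0.869% for HEB. Seen from the open regions, 2947 of the 48320 DNaseI regions carried TCF1, or 6.1% (5.89 to 6.32%), and 1658 carried HEB, or 3.43% (3.27 to 3.60%).

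**Figure D1:**
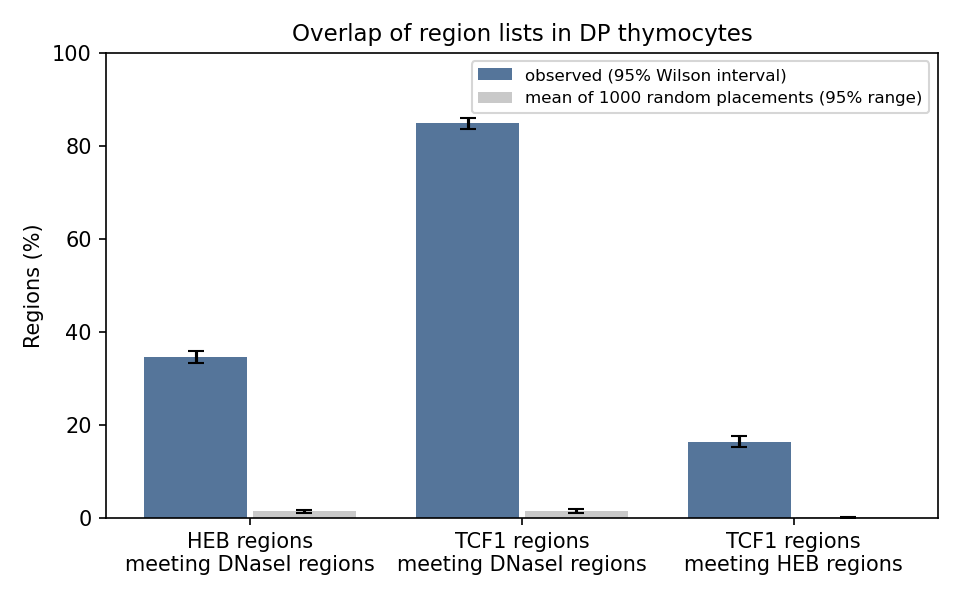
Bars give the percentage of regions of 1 list that met a region of another by at least 1 bp (blue, with 95% Wilson intervals) and the mean of 1000 random placements (grey, with their 95% range). TCF1 regions met DNaseI regions in 84.9% of cases, HEB regions in 34.5%, and TCF1 regions met HEB regions in 16.3%, each above its placed value.

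The location of HEB regions went with their score. Among 2015 HEB regions with scores of 9 or 10, 15.8% (14.3 to 17.5%) lay in DNaseI regions, and this share was 61.1% (55.9 to 66.1%) at scores of 15 to 16 and 83.3% (64.1 to 93.3%) among the 24 regions above 50. The lowest-scoring HEB regions were still 11.8-fold above random placement (p = 0.002 by permutation of positions). For TCF1 the share was above 80% in every score bin, with 83.1% (79.3 to 86.3%) of those at scores of 7 to 8 and 89.4% (79.7 to 94.8%) of those at 31 to 60. The median HEB score was 15 inside and 10 outside DNaseI regions, a difference of 5 (95% interval 3 to 5, permutation test, adjusted p = 1.5e-05). The median TCF1 score was 11 inside and 10.5 outside, a difference of 0.5 (0 to 1, adjusted p = 0.00547 by permutation).

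**Figure D2:**
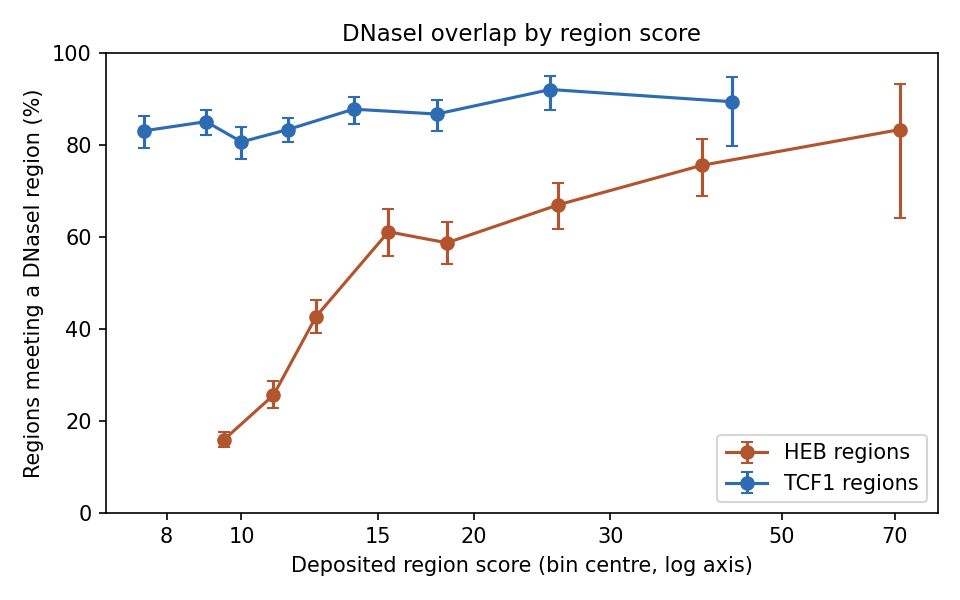
Points give the percentage of HEB (brown) and TCF1 (blue) regions that met a DNaseI region (y axis) within bins of the deposited region score (x axis, log scale), with 95% Wilson intervals. The HEB share ran from 15.8% in the lowest bin to 83.3% in the highest, while the TCF1 share lay between 80.7 and 92.1%.

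The second comparison asked whether both factors occupied the same open regions. HEB and TCF1 regions overlapped in 578 cases, which was 16.3% (15.1 to 17.6%) of TCF1 regions and 11.7% (10.9 to 12.7%) of HEB regions. Placement of TCF1 regions on their chromosomes gave a mean of 2.78 overlaps, so the observed number was 208-fold higher (permutation of positions, p = 0.002). In another placement, TCF1 regions in open chromatin went into DNaseI regions drawn at random, unmatched on width or score. The other TCF1 regions were placed on their chromosomes. The mean was 51.6, and the observed number was 11.2-fold above it (p = 0.002 by permutation of positions). The first of these values was 107-fold against local shifts of 20 to 200 kb, 67.3-fold with a gap of up to 500 bp, 324-fold when at least 50% of the shorter region had to overlap, and 542-fold with scores above each list's median.

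Among DNaseI regions, 619 carried both factors, 1039 carried HEB without TCF1, 2328 carried TCF1 without HEB, and 44334 (91.8%) carried neither. The odds of TCF1 were 4.64 times higher in DNaseI regions with HEB than in those without (95% interval 4.12 to 5.21, Mantel-Haenszel over width deciles). Permutation of the TCF1 mark within chromosome, width and score strata gave a mean of 304 shared regions (95% range 277 to 331), against the 619 observed (p = 0.0002, the smallest possible). Without strata the odds ratio was 11.3 (10.2 to 12.6), and over strata of chromosome, width and score it was 3.97 (3.51 to 4.50). In DNaseI regions of 300 bp or less it was 12.5 (7.75 to 20.3), from 21 shared regions.

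Regions that met the other factor mostly lay in open chromatin. Of HEB regions that met a TCF1 region, 92.9% (90.5 to 94.7%) lay in DNaseI regions, against 26.7% (25.5 to 28.1%) of the other HEB regions. A HEB region that met a TCF1 region shared its position, and 84.9% of all TCF1 regions lay in DNaseI regions, so a large difference follows from the overlap itself. With scores above each list's median these HEB shares were 92.1% and 47.2%. Of TCF1 regions that met a HEB region, 93.1% (90.7 to 94.9%) did so, against 83.3% (81.9 to 84.6%) of the other TCF1 regions (adjusted p = 1.44e-10, Fisher's exact test). This difference of 9.79 points was 6.21 points with a gap of up to 500 bp and 14.9 points with scores above each list's median. The median HEB score was 16 with TCF1 and 11 without, a difference of 5 (5 to 6, permutation test, adjusted p = 1.5e-05). Within DNaseI regions these medians were 16 and 13 (p = 4e-05 by permutation). The median TCF1 score was 12 with HEB and 11 without (difference 1, interval 0 to 1, adjusted p = 0.00381 by permutation).

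DNaseI regions that carried a factor had higher scores and were wider than those with neither. The median DNaseI score was 15 (quartiles 10 and 29) with neither factor, 42 (24 and 69) with HEB alone, 50 (28 and 80) with TCF1 alone and 91 (52 and 147) with both. Regions with both exceeded those with HEB alone by 49 (42 to 54) and those with TCF1 alone by 41 (35.0 to 46), each with an adjusted p of 1.5e-05 in permutation tests. Regions with TCF1 alone exceeded those with HEB alone by 8 (4 to 10, adjusted p = 0.000437 by permutation). Median widths were 306 bp with neither factor, 687 bp with HEB alone, 677 bp with TCF1 alone and 1053 bp with both. Because the score followed the width, scores were also ranked within width deciles. There, regions with HEB alone stood 8.48 percentile points and those with TCF1 alone 19.3 points above those with neither. Regions with both factors stood 22.4 points above those with HEB alone and 12.5 points above those with TCF1 alone (p = 0.002 each by permutation, the smallest possible). Widths still differ inside a decile, so part of these gaps may reflect width. TCF1 was found on 0.660% (0.488 to 0.891%) of DNaseI regions at the lowest score of 8 and on 55.6% (50.9 to 60.1%) of the 441 regions above 150. The corresponding HEB shares were 0.566% (0.409 to 0.782%) and 42.0% (37.4 to 46.6%).

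**Figure D3:**
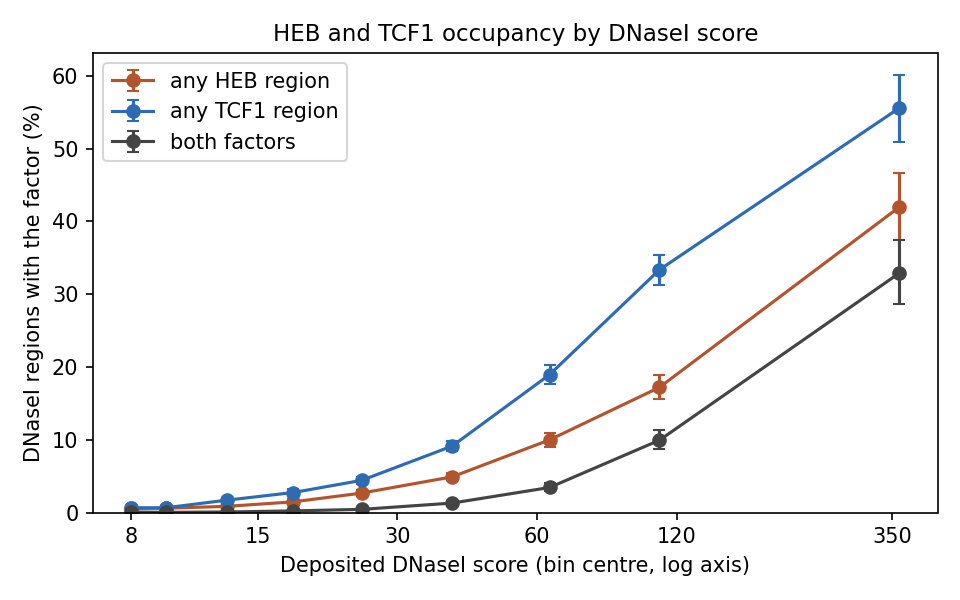
Points give the percentage of DNaseI regions that carried HEB, TCF1 or both (y axis) within bins of the deposited DNaseI score (x axis, log scale), with 95% Wilson intervals. In the highest bin 55.6% carried TCF1, 42.0% HEB and 32.9% both, against 0.660%, 0.566% and 0.0785% at a score of 8.

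The third comparison described how the regions were arranged. Regions of each list lay close to others of the same list more often than placed regions. A neighbour within 10 kb was found for 78.7% of DNaseI regions, 16.5% of HEB regions and 21.3% of TCF1 regions, which was 2.22-fold, 4.07-fold and 6.98-fold above placement (permutation of positions, p = 0.002 each). Within 2 kb these values were 5.42-fold, 8.00-fold and 11.4-fold, and within 50 kb they were 1.11-fold, 1.95-fold and 3.15-fold (p = 0.002 each by permutation of positions). Against DNaseI regions drawn at random, clustering was 2.86-fold higher for the 1701 HEB regions in open chromatin and 1.43-fold higher for the 3010 TCF1 regions there (p = 0.002 each, permutation over DNaseI regions). Only 1658 DNaseI regions carried HEB and 2947 carried TCF1, so some factor regions shared a DNaseI region and counted as neighbours. DNaseI regions with a factor were also wider and higher-scoring than those with neither. Part of these values may come from both.

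The 10 windows of 100 kb richest in factor regions held 9 to 13 of them, against a mean of 0.330 per window. The window from 54800001 to 54900000 of chromosome 14 came first, with 12 TCF1 regions, 1 HEB region and 44 DNaseI regions. On chromosome 7, the window from 71100001 to 71200000 held 6 HEB and 5 TCF1 regions, that from 149500001 to 149600000 held 6 and 4, and that from 132700001 to 132800000 held 4 and 5. Adjacent windows of chromosome 6 were both among the 10: 71200001 to 71300000 held 6 HEB and 5 TCF1 regions, and 71300001 to 71400000 held 6 and 3. The window from 125200001 to 125300000 of chromosome 8 held 7 HEB and 2 TCF1 regions, and that from 47600001 to 47700000 of chromosome 17 held 3 and 6. The windows from 43800001 to 43900000 of chromosome 9 and from 101800001 to 101900000 of chromosome 2 held 4 HEB with 5 TCF1 and 5 HEB with 4 TCF1 regions. The last of these tied, at 9 factor regions and 21 DNaseI regions, with the window from 108300001 to 108400000 of chromosome 12 (3 HEB and 6 TCF1 regions), and came first by position.

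**Figure D4:**
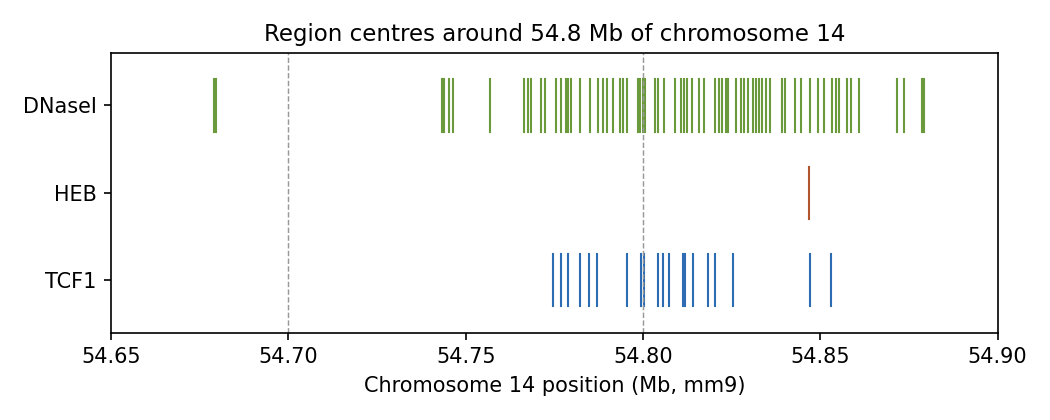
Ticks mark the centres of DNaseI, HEB and TCF1 regions along chromosome 14 (x axis, Mb, build mm9), and dashed lines mark the borders of the 100 kb windows. The window that starts at 54800001 held 12 TCF1 regions, 1 HEB region and 44 DNaseI regions.

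The highest-scoring DNaseI region lay on chromosome 11 from 52088379 to 52096224, with a width of 7846 bp and a score of 871, and it carried 1 HEB and 1 TCF1 region. The next were on chromosome 2 from 31916687 to 31921445 (score 555, with 2 HEB regions and 1 TCF1 region) and on chromosome 14 from 54845340 to 54848697 (score 555, with 1 of each). The fourth, on chromosome 15 from 74784490 to 74791267 (score 521), carried neither factor, and the fifth, on chromosome 8 from 108145095 to 108148814 (score 508), carried 2 of each.

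The 5 highest-scoring HEB regions all lay in DNaseI regions and all met a TCF1 region. They were on chromosome 16 from 32660309 to 32660509 (score 99), chromosome 11 from 97861770 to 97861970 (76) and from 117813555 to 117813755 (75), chromosome 3 from 9886949 to 9887149 (73) and chromosome 10 from 98594928 to 98595128 (73). The 5 highest-scoring TCF1 regions also lay in DNaseI regions, and 2 of them met a HEB region: chromosome 6 from 41504396 to 41504578 (score 60) and chromosome 1 from 191655000 to 191655182 (48). The other TCF1 regions were on chromosome 3 from 130639978 to 130640160 (58), chromosome 19 from 59492669 to 59492851 (52) and chromosome 2 from 32633717 to 32633899 (51).

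The density of open regions varied between chromosomes. Among autosomes it was highest on chromosome 11, with 38.5 DNaseI regions per Mb (95% Poisson interval 37.4 to 39.7), 2.78 HEB regions per Mb (2.49 to 3.10) and 2.51 TCF1 regions per Mb (2.23 to 2.81). The lowest autosomal DNaseI density was on chromosome 3, at 12.5 per Mb (12 to 13.1). The X chromosome held 2.5 DNaseI regions per Mb, 0.126 times the autosomal 19.9 per Mb (95% exact interval of the ratio 0.114 to 0.139). The corresponding ratio was 0.130 (0.0882 to 0.185) for TCF1 and 0.315 (0.257 to 0.383) for HEB. With scores above each list's median, a setting chosen after seeing the data, the HEB ratio was 0.523. Of the 103 HEB regions on X, 1 lay in a DNaseI region, or 0.971% (0.172 to 5.30%), against 35.3% (34.0 to 36.7%) of those on autosomes. Of the 31 TCF1 regions on X, 17 did, or 54.8% (37.8 to 70.8%), against 85.2% (84.0 to 86.4%) on autosomes. The Y chromosome, whose regions spanned 2.30 Mb, held 4 DNaseI, 12 HEB and 4 TCF1 regions, and no factor region there met a DNaseI region. Its HEB density of 5.23 per Mb (2.70 to 9.13) was the highest of any chromosome, though from 12 regions over a short span.

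**Figure D5:**
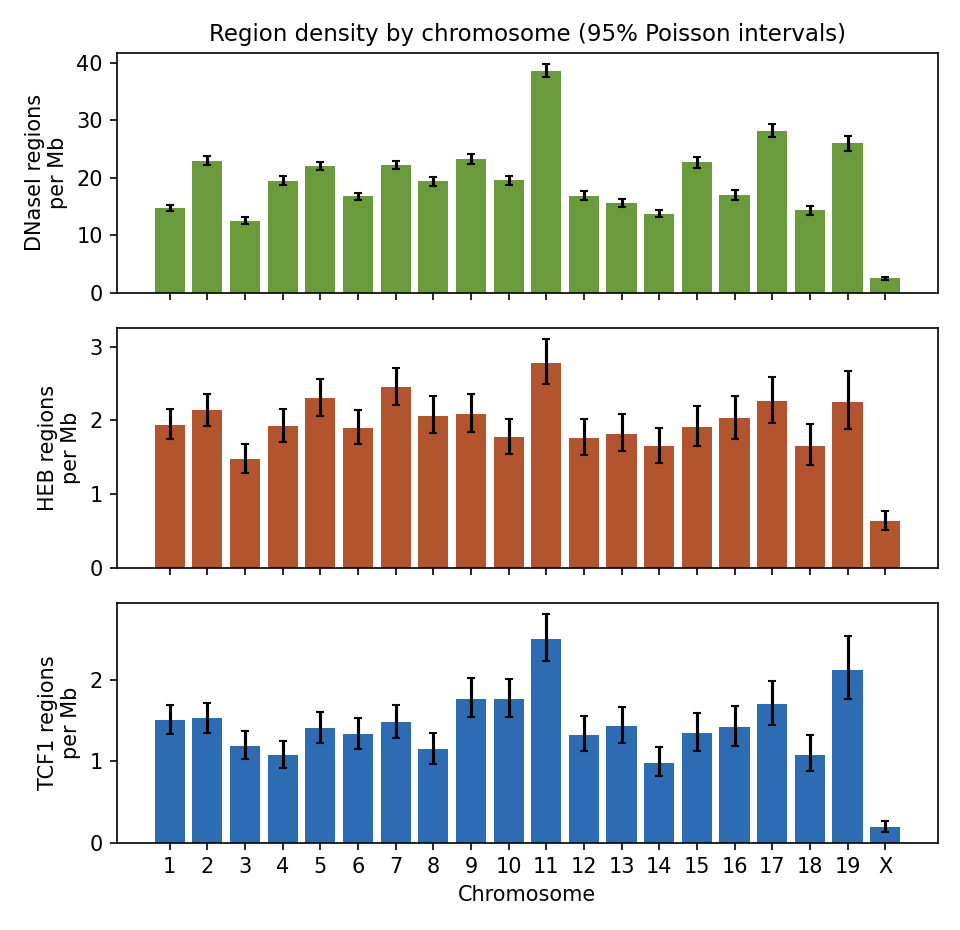
Bars give regions per Mb (y axes) on each autosome and on X (x axis) for the DNaseI, HEB and TCF1 lists, with exact 95% Poisson intervals. Of the chromosomes shown, chromosome 11 had the highest density in each list and X the lowest, at 2.5 DNaseI, 0.631 HEB and 0.190 TCF1 regions per Mb.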

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

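The X chromosome tests and the gap between the factors at stricter scores were chosen after the results were seen; the tests of TCF1 at weak DNaseI regions and of density over the autosomes were written before, and the matching on HEB score and the split at HEB scores of 10 or less were added afterwards.

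TCF1 and HEB differed in how often they lay in open chromatin. The share in DNaseI regions was 50.4 percentage points higher for TCF1 (84.9%) than for HEB (34.5%), with a 95% interval of 48.6 to 52.2 points, and 27.3 points higher (24.3 to 30.3) with scores above each list's median. The factors also differed in how that share went with the score. Above-median HEB scores had 5.66 times (4.98 to 6.43) the odds of lying in a DNaseI region that other HEB scores had, and for TCF1 this odds ratio was 1.45 (1.19 to 1.76). The ratio of these odds ratios was 3.91 (3.10 to 4.94, p = 0.0002 by permutation of the score class within each list, the smallest possible). That permutation assumes no dependence on the score in either list, so the interval, and not the p-value, bears on the difference between factors.

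The 3229 HEB regions outside DNaseI regions are the main part of that gap. The test of open regions missed by the DNaseI list used its weakest regions as the standard. TCF1 was found at 1.27% (0.937 to 1.72%) of HEB regions outside DNaseI regions. Among the 74 HEB regions in DNaseI regions with scores of 10 or less it was 9.46% (4.66 to 18.3%). This difference also held at equal HEB scores (odds ratio 3.97, 1.49 to 10.6, p = 0.0172 by permutation). It rests on 7 shared regions and is undecided at HEB scores of 10 or less (5 of 1696 against 0 of 31, the latter allowing up to 11%). These values argue against missed regions like the weakest listed ones as the whole source. Missed regions weaker than those stay open. Over all DNaseI regions, with or without HEB, the TCF1 share was 1.71% for scores of 11 to 15, 0.661% for 9 to 10 and 0.660% for 8. Among DNaseI regions with HEB, 9 of 90, 2 of 38 and 5 of 36 carried TCF1 at these scores. These few regions showed no steady fall with the score, so the share expected at still weaker regions is unknown. For background spread by chromosome length, the log density of HEB regions outside DNaseI regions was set against the log DNaseI density over 19 autosomes. The slope was 0.209 (95% bootstrap interval 0.086 to 0.387), neither 0 nor above 0.5, so the rule written before gave no verdict. Without chromosomes 11 and 3 it was 0.161. HEB regions in DNaseI regions had a slope of 0.975 (0.703 to 1.23), which their selection by the DNaseI list largely fixes. For TCF1 regions outside DNaseI regions the slope was 0.0358 (-0.477 to 0.419), with an interval that includes the HEB value. In a comparison added afterwards, 41 of the 3229 HEB regions outside DNaseI regions met TCF1. Random placement of all 4930 HEB regions met a mean of 2.69 TCF1 regions (95% range 0 to 7). Of HEB regions that met TCF1, 537 of 578 lay in DNaseI regions on all chromosomes and 537 of 570 on autosomes. Some of the 41 therefore lay on X or Y. These values argue against background spread evenly by length as the whole source, and such background stays open as a part. They cannot tell bound sites from other positions that both lists share, and unmasked sequence lowers the placed mean. A mixture of background and bound sites in closed chromatin may give such values, no test here separates them, and no biological explanation was tested.

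The X chromosome held few open regions, at 0.126 times the autosomal density for DNaseI. If the score scaled with reads and the lowest score were the calling threshold, halved reads from 1 X copy per cell would leave the 51.9% of regions with scores of 16 or more, far above the X ratio, but neither condition is known, so this explanation stays open. A loss of X reads alike in every library stays open for the same reason. The X to autosome ratio was 0.315 (0.257 to 0.383) for HEB, above the DNaseI interval of 0.114 to 0.139. It was 0.130 (0.0882 to 0.185) for TCF1, close to the DNaseI ratio. The HEB value joined unlike parts: 0.482 (0.392 to 0.587) outside DNaseI regions and 0.00866 (0.000219 to 0.0483) in them. The latter rests on 1 region on X. For TCF1 these ratios were 0.398 (0.216 to 0.674) and 0.0836 (0.0487 to 0.134). In each factor list, only regions outside DNaseI regions lay above the DNaseI interval. On the conditions given above, halving would leave 7.96% of autosomal HEB regions outside DNaseI regions, below their X ratio. The mouse sex is not given in the labels used here, and gene density could not be used without an mm9 annotation. Each list held regions on Y (4 DNaseI, 12 HEB and 4 TCF1), but misplaced reads were not tested for, so these do not settle the sex. No biological explanation was tested.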

How the results depend on the processing

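All 68 tested alternatives over 18 results kept their direction and their side of the 0.05 threshold. They are not independent checks, and some could hardly differ. The rules of 50% overlap and of midpoints gave the same values for overlap and co-occupancy. The joint strata kept the p-value of the main permutation. A large HEB share difference between regions with and without TCF1 follows from the overlap itself. HEB regions met DNaseI regions in 33.1% of cases when at least 50% of the shorter region had to overlap and also when the region's midpoint had to lie inside (both rules gave the same value), in 36.1% with a gap of up to 500 bp, and in 52.4% with scores above each list's median. The corresponding TCF1 values were 79.6%, 79.6%, 88.7% and 79.7%, and TCF1 regions met HEB regions in 13.7%, 13.7% and 19% of cases under the first 3 rules. The gap between TCF1 and HEB in DNaseI regions was 46.5 points under each of the first 2 rules, 52.6 points with the 500 bp gap and 27.3 points with scores above the median. The stricter score removes weak DNaseI regions too, which by construction lowers the TCF1 share. The X to autosome ratio of HEB regions was 0.523 with scores above the median. At that score the number of factor regions moved by over 1.5 times in 4 of the 10 named windows. It was 5 in the chromosome 7 window at 71100001 and 6 in that at 149500001. It was 4 each in those at 47600001 of chromosome 17 and 43800001 of chromosome 9. The filter kept 2050 of the 4930 HEB and 1401 of the 3546 TCF1 regions in all, so falling counts follow from the filter itself. Settings added after seeing the data were the HEB score classes, TCF1 placed inside DNaseI regions, the joint strata, narrow DNaseI regions, width deciles, the windows and X ratios at stricter scores, and the gap between the factors under other rules. The planned promoter, annotation, gene list and motif alternatives were not run, because no mm9 annotation or sequence was used here. No library could be left out, since each assay had 1 sample, and no paired analysis was possible because no group had replicates. Unknown depth limits what the absence of a region in a list can show.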

Other observations

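The test of a score factor was chosen after the data were seen, as was the naming of windows outside the 10 richest; the test of centre distances was written before its result was seen.

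A stretch of chromosome 14 held many TCF1 regions and few HEB regions. The adjacent windows from 54700001 to 54800000 and from 54800001 to 54900000 held 8 and 12 TCF1 regions, 0 and 1 HEB regions, and 26 and 44 DNaseI regions. TCF1 made up 41.8% of all factor regions. On chromosome 2, the window from 117200001 to 117300000 held 7 TCF1 regions and 1 HEB region. These were the windows most skewed to TCF1 among the 22 with at least 8 factor regions. No p-value is given, because regions of each list lay in clusters and are not independent draws, and no gene was assigned, since no mm9 annotation was used here.

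Within open regions that carried 1 HEB and 1 TCF1 centre, the factors lay close together. Over 550 such DNaseI regions, with a median width of 1005 bp, the median distance between centres was 54 bp (quartiles 23 and 107), and 48.5% of pairs lay within 50 bp. Exchanging the TCF1 positions among shared regions of like width gave a median of 182.5 bp (95% range 165.5 to 198.5) and 16.2% within 50 bp (13.5 to 19.1), with p = 0.0002 by permutation, the smallest possible. The value of 54 bp therefore argues against both factors being centred on the open region independently of each other. Binding to neighbouring motifs, recovery of 1 factor through the other, and a shared pull towards the most accessible point of the region may each give this closeness, and they were not told apart.

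Some whole numbers never occurred among the HEB scores. Of the values from 9 to 45, the 99th percentile, 14, 21, 28, 35 and 43 were absent, and DNaseI and TCF1 scores had no such gaps up to their 99th percentiles. A candidate explanation is that tag numbers were multiplied by 1 factor, between 1.1613 and 1.1621, and then cut to whole numbers. Rounding to the nearest whole number was tried first and 0 factors gave these gaps; cutting was tried next, after the gaps had been seen, so only the higher values test it. Of the 47 HEB regions above 45, 0 fell on the 6 higher values that every such factor skips, where a geometric decline fitted to these scores would put 5.70 and the mean of the values on either side would put 5.5. The unit of the score remains unstated, and this reading of it is a hypothesis.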
